A study of Mus musculus with 8 samples.

How the data were processed

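RNA from 8 mouse livers was hybridised to Affymetrix one-colour arrays in 3 groups. GF mice were raised without microbes (3 arrays), CONV mice were raised germ-free and then given microbes, which the labels also call transfaunation (3 arrays), and SPF mice were raised free of specific pathogens but with microbes (2 arrays). Biotin-labelled cRNA was made from 1 µg of total RNA, per the labels' protocols. Group and replicate number were taken from the sample titles. The labels call the arrays of a group biological replicates and say nothing more about the animals, so the p-values measure the spread between these arrays.

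The deposited table holds 1 value per probe set and array for 45037 probe sets, with no missing value and no control probe set. Per the submitters' processing notes, the authors used affy and RMA, which corrects background, quantile-normalises the arrays and summarises probes to probe sets. No version, chip annotation or filter is given in the sources used here. The log2 scale of the deposited values was read from their range, 2.76 to 15.23, and was not stated. Array medians lay between 5.32 and 5.37. For arrays, their number limits the precision.

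Probe sets were named from the platform annotation supplied with the table. A single gene symbol was listed for 34945 probe sets, several for 932 and none for 9160. Of the gene identifiers, 34741 matched a mouse gene table of assembly GRCm38.p6, which was used for names only; 204 did not match and kept the listed symbol. No symbol changed. Probe sets with several symbols or none were left out of the gene results. A gene was represented by its probe set with the highest mean over the 8 arrays, and was tested if that probe set lay above the 40th percentile of the array on at least 2 arrays. This kept 14048 of 18193 genes. Probe sets whose identifier ends in _s_at or _x_at can match several transcripts; among the named genes these represented Saa2, Apoa4, Erdr1, Ctse, Hamp2, Lss, Fdft1, Ildr2 and Dbp. Signals of near-identical family members, such as Saa1 and Saa2, the Cyp2b genes or the Cyp2c genes, are uncertain for the same reason.

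Differences were tested on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes). All 8 arrays entered 1 model with 3 groups and no covariate, because SPF had 2 arrays and the groups then share 1 estimate of the spread. Benjamini-Hochberg adjustment ran over the 14048 genes of each comparison, and the threshold was an adjusted p of 0.05. The comparisons were SPF against GF, CONV against GF and CONV against SPF. The first and second of these share the 3 GF arrays, so their overlap was set beside 50 simulations of unchanged groups against shared controls, beside the overlap of independent lists, and beside splits of the GF arrays.

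A total of 41 gene lists with 669 entries was fixed before the data were examined. They cover clock, metabolic, detoxification, immune and stress genes and markers of liver and other cell types. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 41 lists of a comparison. Camera with an estimated correlation and fry, which tests a list without comparing it with other genes, were run beside it. Counts within a list are given over all genes tested and adjusted over the list alone. A median over a list describes its members, which are not independent replicates.

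The genes to name were also fixed by a rule before the data were examined. For each comparison the rule took the 10 largest rises and the 10 largest falls past the threshold whose groups did not overlap, or the 5 smallest p-values in a direction with fewer than 5 calls. It added up to 4 members past the threshold from each list, and always Arntl, Clock, Per1, Per2, Cry1, Nr1d1 and Dbp, because the series title speaks of diurnal patterns. Genes with clone-like symbols were counted and not named.

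The code was tested on simulated data with 200 changed genes among 14048, in 5 draws. For CONV against GF, 79.4% of genes changed 1.5-fold and 98% of genes changed 2-fold were recovered, with a mean of 9 unchanged genes called. For SPF against GF these values were 70%, 96.2% and 11.6. The simulated genes varied independently and with the same spread in every group, unlike those on the real arrays. These shares therefore check the code and do not give the power of the real comparisons. Alternatives covered the arrays in the fit, the replicate number as a block, the low-signal filter, the choice of probe set, variance moderation, array weights, normalisation, the threshold, the set test and leaving out each array in turn. A few results for gene lists without single arrays were added after the data were seen. All per-sample columns of the table were used.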

Results

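Liver transcript levels were measured on 8 arrays from germ-free mice (GF, n = 3), ex-germ-free mice that had been given microbes (CONV, n = 3) and specific pathogen-free mice (SPF, n = 2). The series title concerns dietary fat, gut microbes and diurnal patterns. Diet, strain, sex, age, the time of day of collection and the time since colonisation are not given in the sources used here. Values are log2 RMA values, differences are log2 differences with the standard error from limma, and adjusted p-values are limma's. The first principal component held 46.1% of the variance over the tested genes. The GF arrays lay between −19.9 and −17.0 on it and the others between 0.64 and 23.2. The arrays within the colonised groups lay far apart on this axis, with SPF replicates 1 and 2 at 23.2 and 2.77 and CONV replicates 1, 2 and 3 at 10.4, 17.6 and 0.64.

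SPF against GF asked which liver transcripts differed between mice raised with and without microbes. SPF livers had higher Saa1, Saa2, Saa3 and Lcn2, higher Marco and Cd5l of the macrophage markers, lower Msmo1, Lss, Fdft1 and Hmgcs1 of cholesterol synthesis, higher Clock and Nfil3 and lower Per1 and Ciart. The largest rise was that of Cyp39a1, an oxysterol 7-alpha-hydroxylase of bile acid synthesis, by 3.47 ± 0.40 (adjusted p = 0.0104), from 6.04 ± 0.55 (SD, n = 3) in GF to 9.51 ± 0.10 (SD, n = 2) in SPF. Saa2, a serum amyloid A of the acute phase, rose by 3.42 ± 0.29 (adjusted p = 0.00299). Among genes past the threshold, the largest fall was that of Erdr1, at −2.81 ± 0.26 (adjusted p = 0.00472).

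In this comparison 323 of 14048 genes passed the threshold, 200 higher and 123 lower in SPF, and 79 of them differed at least 2-fold. With each array centred on its 75th percentile the split was 163 higher and 234 lower. Besides Cyp39a1 and Saa2, the largest rises were those of Slc3a1 (2.65), a subunit of a cystine and dibasic amino acid transporter, the apolipoprotein Apoa4 (2.58), Saa1 (2.55), the vesicle-priming factor Unc13b (2.50), the Arf GTPase-activating protein Asap2 (2.33), Saa3 (2.22), the siderophore-binding Lcn2 (2.16) and Papss1 (2.07), which makes the sulfate donor of sulfotransferases. After Erdr1, the largest falls were those of the matrix proteoglycan Omd (−2.02), the cytochrome Cyp2g1 (−2.0), the clock repressor Ciart (−1.96), Cnmd (−1.96), the glutathione peroxidase Gpx6 (−1.93), the noncoding Hectd2os (−1.87), the aspartic protease Ctse (−1.84), the caveolar protein Cav1 (−1.82) and the hepcidin Hamp2 (−1.65). A second, dimmer probe set did not show the difference for Ctse (−0.16), Hamp2 (0.20) or Marco (0.24). The count depended on single arrays. It was 26 without SPF replicate 1, 539 without SPF replicate 2, 105, 83 and 49 without GF replicate 1, 2 or 3, and 175 without CONV replicate 1, while 11 of the 45 named genes past the threshold kept their call in all 8 such fits.

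Of 21 measured clock genes, 2 rose, 2 fell and 17 did not pass in SPF against GF. Adjusted over the list alone, 3 rose and 9 fell. Clock, a transcriptional activator of the core loop, rose by 1.04 ± 0.11 (adjusted p = 0.00644), and Nfil3, a repressor of D-box genes, rose by 1.34 ± 0.26 (adjusted p = 0.0423). Per1, a repressor of the core loop, fell by 1.18 ± 0.23 (adjusted p = 0.0415) and Ciart by 1.96 ± 0.28 (adjusted p = 0.0187). The other core genes did not pass: Arntl, the partner of Clock, differed by 1.65 (adjusted p = 0.0860), Per2 by −1.93 (adjusted p = 0.0570), the output gene Dbp by −2.57 (adjusted p = 0.0906), Cry1 by 0.40 (adjusted p = 0.524) and Nr1d1 by −0.39 (adjusted p = 0.323). A second probe set of Arntl differed by −0.14, and others of Per2 by −0.53 and −0.36. Activators and repressors of the clock move in opposite directions, so a one-way test of the list says little (camera adjusted p = 0.0723). Fry's test for change in either direction gave the list an adjusted p of 0.00875. That fry test also passed for hepatocyte markers (adjusted p = 0.0337) and oxidative phosphorylation (adjusted p = 0.0170). It did not pass for liver endothelium (adjusted p = 0.574). A pass in it therefore does not set the clock list apart. The SPF replicates stood apart in these genes, with Dbp at 8.41 and 11.1 and Arntl at 8.23 and 6.54. Without SPF replicate 1, 3 clock genes fell over the list alone and the list's median was −0.11 in place of −0.39; without SPF replicate 2 the median was −0.66. The one-way test passed without GF replicate 1, CONV replicate 3 or SPF replicate 2 (camera adjusted p = 0.0473, 0.0432 and 0.0193).

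**Figure D1:**
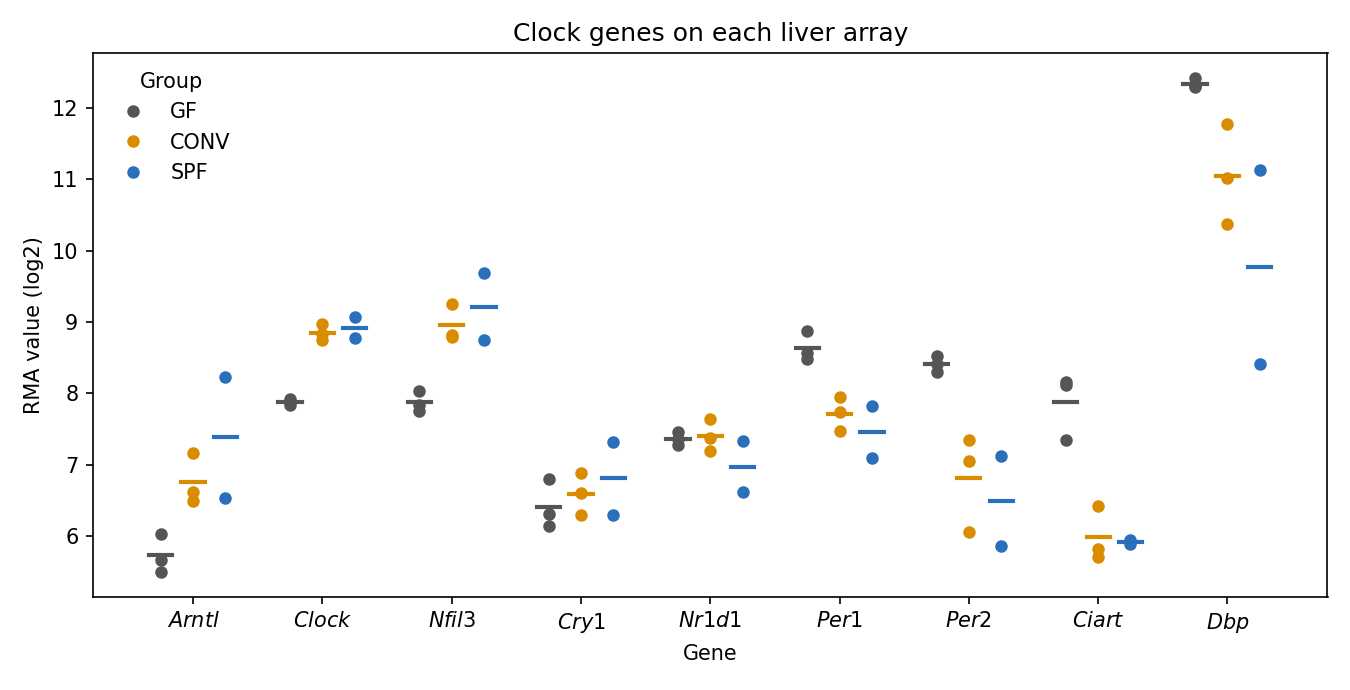
Log2 RMA values (vertical axis) of 9 clock genes (horizontal axis) on each of the 8 liver arrays, with points for arrays and bars for group means of GF (n = 3), CONV (n = 3) and SPF (n = 2). Clock lies at 7.88 in GF, 8.85 in CONV and 8.92 in SPF, and the 2 SPF arrays are at 8.41 and 11.1 for Dbp.

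The cholesterol synthesis list fell in SPF against GF (camera adjusted p = 4.75e-13), although its adjusted p was 0.584 with an estimated correlation. All 18 measured members had lower means in SPF, with a median of −0.62. Of these, 4 fell and 14 did not pass; adjusted over the list alone, 16 fell. Msmo1, a sterol C4-demethylase, fell by 0.86, lanosterol synthase Lss by 0.78, squalene synthase Fdft1 by 0.64 and Hmgcs1, which makes HMG-CoA, by 0.60. Other probe sets differed by −1.49 and −0.47 for Lss. For Fdft1 a bright one differed by −0.855 and dim ones by −0.07 and −0.15. Over all genes 0 of these fell in limma without any 1 GF array or without SPF replicate 1, 1 fell without CONV replicate 2 and 11 without CONV replicate 3, with 16 of 18 at an unadjusted p under 0.05 in the full fit. The sterol exporters Abcg5 and Abcg8 fell by 1.15 and 0.80, and Akr1d1, a 5-beta-reductase of bile acid synthesis, fell by 0.46, with a second probe set at −0.69. In the bile acid list 1 of 22 members rose and 3 fell, and adjusted over the list alone 2 rose and 5 fell (camera adjusted p = 0.209).

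The Kupffer cell and macrophage markers were higher in SPF livers as a list (camera adjusted p = 1.02e-08; adjusted p = 0.584 with an estimated correlation). All 14 had higher means, with a median of 0.93. The scavenger receptor Marco rose by 1.22 ± 0.22 and Cd5l, a macrophage secretory protein, by 1.05 ± 0.19 (both adjusted p = 0.0364), and 12 did not pass; adjusted over the list alone, 12 of 14 rose. Without SPF replicate 1 that number was 2 and the median 0.55. Over all genes, 9 rose without SPF replicate 2, and 0 rose in limma without any other 1 array except CONV replicate 3; 13 of 14 had an unadjusted p under 0.05. Markers of other cell types differed less, with medians of 0.01 for hepatocytes, 0.02 for liver endothelium, 0.14 for stellate cells and fibroblasts, 0.12 for neutrophils and monocytes, 0.10 for T and NK cells and 0.01 for B and plasma cells.

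The acute phase list rose (camera adjusted p = 1.29e-05; fry adjusted p = 0.0136), with an adjusted p of 0.347 with an estimated correlation. The rise was uneven over the members, with a median of 0.19 and a mean of 0.58. It was largest in Saa2, Saa1, Saa3 and Lcn2 among the members past the threshold. Of 24 members 6 rose and 18 did not pass; adjusted over the list alone, 9 rose and 1 fell. Over all genes 3 rose without any 1 GF array, without CONV replicate 1 or without SPF replicate 1. The macrophage markers given above were higher in the same arrays. Among other immune genes, Bst2, an interferon-induced membrane protein, rose by 0.71 and Myd88, the adaptor of Toll-like receptors, by 0.40. In the interferon list 1 of 23 passed, and in the microbial sensing list 1 of 14, with 1 and 2 rising when adjusted over the list alone (camera adjusted p = 0.145 and 0.0726).

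Another 3 lists passed in SPF against GF. PPAR-alpha targets and fatty acid oxidation were lower (median −0.17, camera adjusted p = 0.00230; adjusted p = 0.630 with an estimated correlation), with a fall of the acyl-CoA thioesterase Acot2 by 0.79; 24 of 25 members did not pass, and 4 fell adjusted over the list alone, a number that was 1 without GF replicate 1 or 3, 2 without GF replicate 2 or CONV replicate 3 and 0 without SPF replicate 1. Target cytochromes of the receptors CAR and PXR were lower as a list (median −0.23, camera adjusted p = 0.00875; adjusted p = 0.584 with an estimated correlation). Its 1 member past the threshold went the other way, with a rise of Cyp3a11, the main mouse CYP3A, by 0.49; adjusted over the list alone, 1 rose and 5 fell, and 2 fell without SPF replicate 1. Cyp2b10, a target of CAR, did not pass over all genes, with a difference of −1.56 on the probe set that represented it. Its other probe sets, which can match several transcripts, differed by −3.17 and −3.12. Cell cycle genes were higher (median 0.43, camera adjusted p = 0.00822; adjusted p = 0.684 with an estimated correlation), with 0 of 19 members past the threshold in limma, over all genes or adjusted over the list alone, 6 at an unadjusted p under 0.05, and differences between −0.12 and 1.16. The median was 0.72 without SPF replicate 2. Without SPF replicate 1 the PPAR-alpha and cell cycle lists did not pass (adjusted p = 0.135 and 0.174; medians −0.10 and 0.27), and 14 lists passed without SPF replicate 2.

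Single members of further lists passed. The fatty acid elongase Elovl3 rose by 1.15 ± 0.09 (adjusted p = 0.00152), the small heat shock protein Hspb1 by 1.82, Hsp90aa1 by 0.68 and the lysosomal protease Ctsc by 1.04. Other probe sets of Hsp90aa1 differed by 1.14, 1.40 and, for a dim one, −0.04, and dim ones of Ctsc by 1.94 and 1.08. The estrogen sulfotransferase Sult1e1 fell by 0.95, the sulfotransferase Sult1d1 by 0.70, the liver glycogen synthase Gys2 by 0.80, the fatty acid desaturase Fads2 by 0.44 and the fatty acid-binding protein Fabp2 by 0.73. The lists that hold these genes did not pass. For the metabolic ones among the 35 lists that did not pass, the median difference was −0.20 for fatty acid synthesis, −0.25 for gluconeogenesis and glycogen, 0.18 for conjugation and glutathione, −0.30 for aryl hydrocarbon receptor targets, −0.06 for amino acid and one-carbon metabolism, −0.02 for oxidative phosphorylation and −0.01 for ribosomal proteins. It was 0.07 for periportal and −0.22 for pericentral hepatocyte genes, and −0.01 for male-biased and −0.23 for female-biased liver genes. It was 0.19 for the unfolded protein list, −0.07 for heat shock, 0.16 for immediate early genes, 0.21 for the growth hormone axis, −0.02 for glucocorticoid targets, 0.07 for antigen presentation and −0.22 for sex-chromosome genes. Lipoprotein genes had a median of −0.002, and the markers of bile ducts, erythroid cells, exocrine pancreas, adipocytes, intestine and skeletal muscle had medians of −0.07, 0.08, −0.23, −0.16, −0.10 and −0.09. In 6 lists, none past the threshold, the median, mean and test differed in sign.

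**Figure D2:**
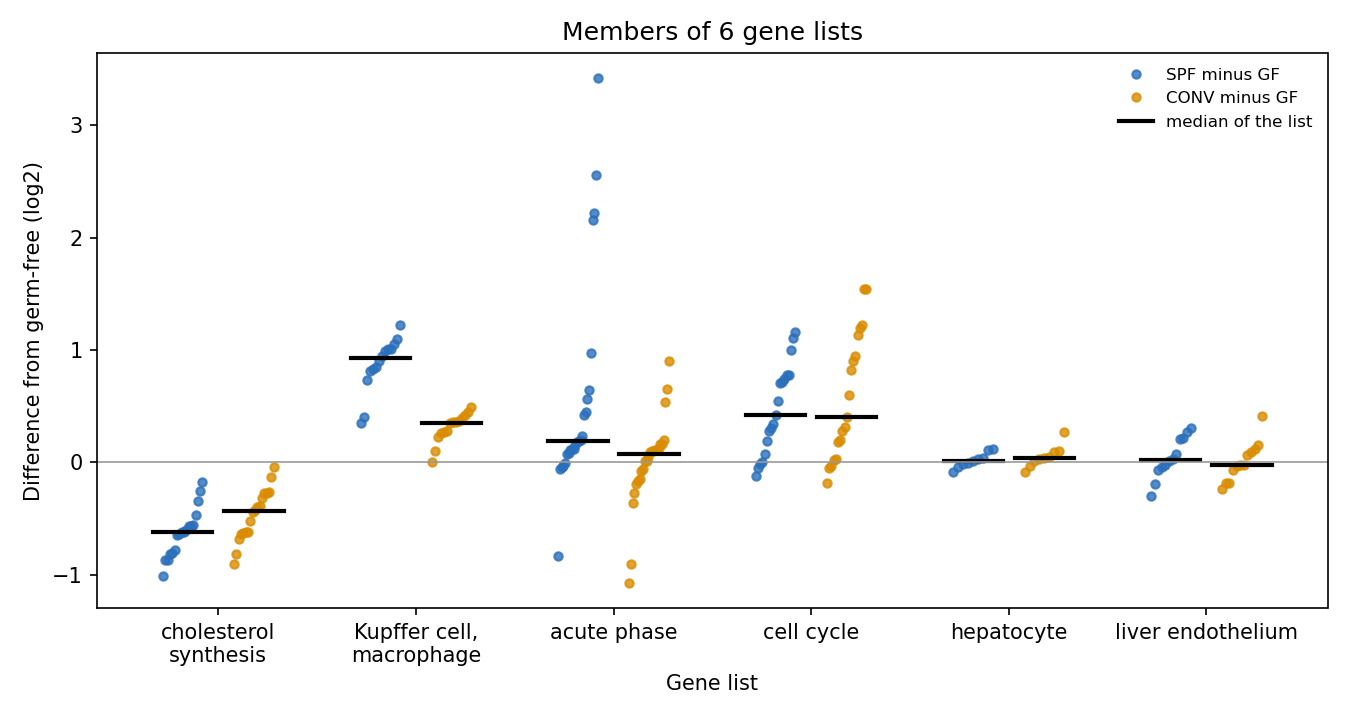
Log2 difference from the GF arrays (vertical axis) of each measured member of 6 gene lists (horizontal axis), for SPF minus GF and CONV minus GF, with a bar at the list's median. The cholesterol synthesis medians are −0.62 and −0.43, the Kupffer cell medians 0.93 and 0.35, and the hepatocyte medians 0.01 and 0.04.

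CONV against GF asked what differed once germ-free mice had been given microbes. CONV livers had higher Cyp39a1, Apoa4, Cish and Csad, and lower Mvk, Msmo1 and Fdft1 of cholesterol synthesis, Cyp2b10 and Ciart, while serum amyloid transcripts did not pass. Cyp39a1 rose by 2.63 ± 0.36 (adjusted p = 0.0275), to 8.66 ± 0.68 (SD, n = 3) in CONV. Cish, a feedback inhibitor of STAT5 signalling, rose by 2.29 ± 0.32 (adjusted p = 0.0275), and Csad, a decarboxylase of taurine synthesis, by 1.73 ± 0.18 (adjusted p = 0.0156). Saa2 differed by 0.54 (adjusted p = 0.277), Saa1 by 0.17 (adjusted p = 0.805), Saa3 by 0.90 (adjusted p = 0.0580) and Lcn2 by −0.14 (adjusted p = 0.850), genes chosen for this comparison after their values were seen.

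Here 329 genes passed, 188 higher and 141 lower in CONV, with 50 of them at least 2-fold. The split was 160 higher and 168 lower with each array centred on its 75th percentile, and 171 and 180 with quantile normalisation applied again. Other large rises were those of Apoa4 (2.18), Slc3a1 (1.71), Dbf4 (1.58), the activator of a replication kinase, Lgalsl (1.56), the kinetochore gene Spc25 (1.42), the cytochrome oxidase subunit Cox7a1 (1.38) and Asap2 (1.35). The largest falls were those of Ciart (−1.89), Cyp2g1 (−1.75), Cyp2b10 (−1.73), a target of CAR, the DNA crosslink repair gene Dclre1a (−1.72), the glycerophosphodiesterase Gpcpd1 (−1.70), the potassium channel Kcnk5 (−1.62), Cav1 (−1.55), Cnmd (−1.5), Omd (−1.41) and Ildr2 (−1.39). Second probe sets of Dclre1a (−0.11) and Spc25 (−0.02) did not show the difference. Another of Kcnk5 was at −0.96, and others of Ildr2 were at −1.153 and, for a dim one, −0.21. The other probe sets of Cyp2b10 differed more, by −3.35 and −2.96. Most calls lay close to the threshold: 278 of the 329 had an adjusted p between 0.03 and 0.05. The count was 22, 20 and 1 without GF replicate 1, 2 or 3, and 10 and 2 without CONV replicate 1 or 2, and none of the 38 named genes past the threshold kept its call in all 8 fits that left out an array (0 of 38; at most 6 of 8 fits).

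Of the clock genes, 1 rose, 1 fell and 19 of 21 did not pass in CONV against GF; adjusted over the list alone, 2 rose and 8 fell. Clock rose by 0.97 ± 0.09 (adjusted p = 0.0156) and Ciart fell by 1.89 ± 0.25 (adjusted p = 0.0258). Per1 differed by −0.92 (adjusted p = 0.0557), Per2 by −1.60 (adjusted p = 0.0660), Arntl by 1.03 (adjusted p = 0.182), Dbp by −1.29 (adjusted p = 0.277), Cry1 by 0.18 (adjusted p = 0.764) and Nr1d1 by 0.04 (adjusted p = 0.923). The model's spread includes the SPF arrays, which varied most in Arntl, Per1 and Per2. The SDs of these genes were 1.197, 0.515 and 0.892 in SPF, 0.273, 0.203 and 0.115 in GF and 0.353, 0.24 and 0.68 in CONV. Their failure to pass is therefore weak evidence against a difference between CONV and GF. Other probe sets differed by −0.03 for Arntl and by −0.43 and −0.22 for Per2. The one-way list test gave an adjusted p of 0.255 and fry's either-way test 0.00653. The either-way fry test also passed for hepatocyte markers (adjusted p = 0.000769) and oxidative phosphorylation (adjusted p = 0.00333). It did not pass for liver endothelium (adjusted p = 0.658), and it does not set the clock list apart. Over the list alone, 3 clock genes fell without CONV replicate 2, 3 without GF replicate 3 and 5 without CONV replicate 1.

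The cholesterol synthesis list fell in CONV as well (median −0.43, camera adjusted p = 1.55e-08; adjusted p = 0.748 with an estimated correlation). Another division of the same 6 arrays into 3 and 3 gave this list a smaller unadjusted camera p, 5.76e-13 against 3.78e-10, while the list's median was at most 0.35 in size over the other divisions. That p is the lowest of the other divisions, which mix GF and CONV arrays unevenly and can keep part of the group difference. It is therefore no chance value for the list. All 18 members had lower means, 3 fell and 15 did not pass; adjusted over the list alone, 15 fell, a number that was 6 without CONV replicate 2, 6 without GF replicate 2 and 7 without CONV replicate 1. The mevalonate kinase Mvk fell by 0.91, Msmo1 by 0.81 and Fdft1 by 0.52. Another bright probe set of Fdft1 was at −0.616, and dim ones were at −0.004 and −0.08. In the bile acid list 2 of 22 rose and 2 fell, and 3 and 2 when adjusted over the list alone: the bile salt export pump Abcb11 rose by 0.42, and Abcg5 and Abcg8 fell by 0.76 and 0.63.

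A further 3 lists passed in CONV against GF. Cell cycle genes were higher (median 0.41, camera adjusted p = 0.000479; adjusted p = 0.748 with an estimated correlation), with 0 of 19 past the threshold in limma over all genes, 10 at an unadjusted p under 0.05 and 7 adjusted over the list alone. That last number was 0 without GF replicate 1, 2 or 3 or CONV replicate 1 or 2, and 11 without CONV replicate 3, while the median was 0.26 without CONV replicate 2 and 0.62 without CONV replicate 3. Conjugation and glutathione genes were higher (median 0.20, camera adjusted p = 0.00697; adjusted p = 0.748 with an estimated correlation), and Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, rose by 0.86; 19 of 20 did not pass, and 7 rose and 1 fell adjusted over the list alone. The number that rose was 3 without GF replicate 1 or CONV replicate 1, 4 without GF replicate 2 and 1 without CONV replicate 2, where the median was 0.10. Macrophage markers were higher (median 0.35, camera adjusted p = 0.0154; adjusted p = 0.753 with an estimated correlation) with 0 of 14 past the threshold in limma under either adjustment and 1 at an unadjusted p under 0.05, and the list did not pass without GF replicate 1 (median 0.16, adjusted p = 0.239) or CONV replicate 3 (median 0.27, adjusted p = 0.186). Other divisions of the same 6 arrays into 3 and 3 gave up to 10 lists past the threshold. Their smallest unadjusted camera p was below that of the groups for each of these lists: 2.81e-07 against 2.34e-05 for cell cycle, 0.000143 against 0.000510 for conjugation and glutathione, and 3.20e-06 against 0.00150 for macrophage markers. The largest medians in size under the other divisions were 0.40, 0.15 and 0.34. Each other division mixes GF and CONV arrays unevenly, so part of the group difference can remain in it. The values given are also the most extreme of these divisions. They are therefore no chance values for the lists and decide nothing about them.

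Among members of the 37 lists that did not pass, Cyp2c54 fell by 1.22 and Cyp3a11 rose by 0.47, and the list of CAR and PXR target cytochromes had 1 rise and 2 falls over all genes and 2 and 7 adjusted over the list alone (camera adjusted p = 0.0686). That list passed without GF replicate 2, CONV replicate 2, SPF replicate 1 or SPF replicate 2 (adjusted p = 0.0344, 0.0192, 0.0186 and 0.0191). The immediate early gene Jun rose by 1.08 and Apoc2, an activator of lipoprotein lipase, by 0.59. Ctsc rose by 0.80 (1.12 and 0.22 on dim probe sets), Elovl3 by 0.96, Bst2 by 0.41 and Myd88 by 0.35. Orm3, an acute phase orosomucoid, fell by 1.07 and Sult1e1 by 1.04. The acute phase list had a median of 0.07 (camera adjusted p = 0.487), with 0 rising and 1 falling over all genes and 1 each adjusted over the list alone.

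The SPF and CONV comparisons share their 3 GF arrays. Of the genes past the threshold in either, 150 passed in both in 1 direction, 95 higher and 55 lower, and 0 passed in opposite directions. They included Cyp39a1, Apoa4, Slc3a1, Clock and Elovl3 among the rises and Ciart, Cyp2g1, Msmo1, Abcg5 and Sult1e1 among the falls. Independent lists of these sizes would share 3.91 genes, a value that leaves out the shared arrays. Simulated unchanged groups against shared controls shared 0 in each of 50 draws, but an adjusted threshold calls next to nothing when no gene changes, so this 0 is no chance value for the 150. The differences correlated over all genes with r = 0.779 against a simulated 0.446, and their covariance was 0.0565 against a simulated 0.00730, a difference of 0.0491. With the GF arrays split between the comparisons, so that none was shared, the covariance was between 0.0475 and 0.0519. The number called in both then had medians of 0 and 2, but with a single GF array limma called 0, 0 and 1 genes in CONV against GF and 17, 4 and 24 in SPF against GF, so these splits do not show how much of the overlap of calls comes from the shared arrays. The number called in both was 17, 15 and 1 without GF replicate 1, 2 or 3, 9 and 2 without CONV replicate 1 or 2, and 15 without SPF replicate 1. Of the 323 genes chosen for passing in SPF 317 had the same sign in CONV, and of the 329 chosen for passing in CONV 326 had the same sign in SPF, shares that the common GF arrays raise. With 2 GF arrays for SPF and the other for CONV, 92 of 105, 78 of 83 and 48 of 49 genes called in SPF had the same sign in CONV, against 65.9%, 64.6% and 66.5% of all genes.

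**Figure D3:**
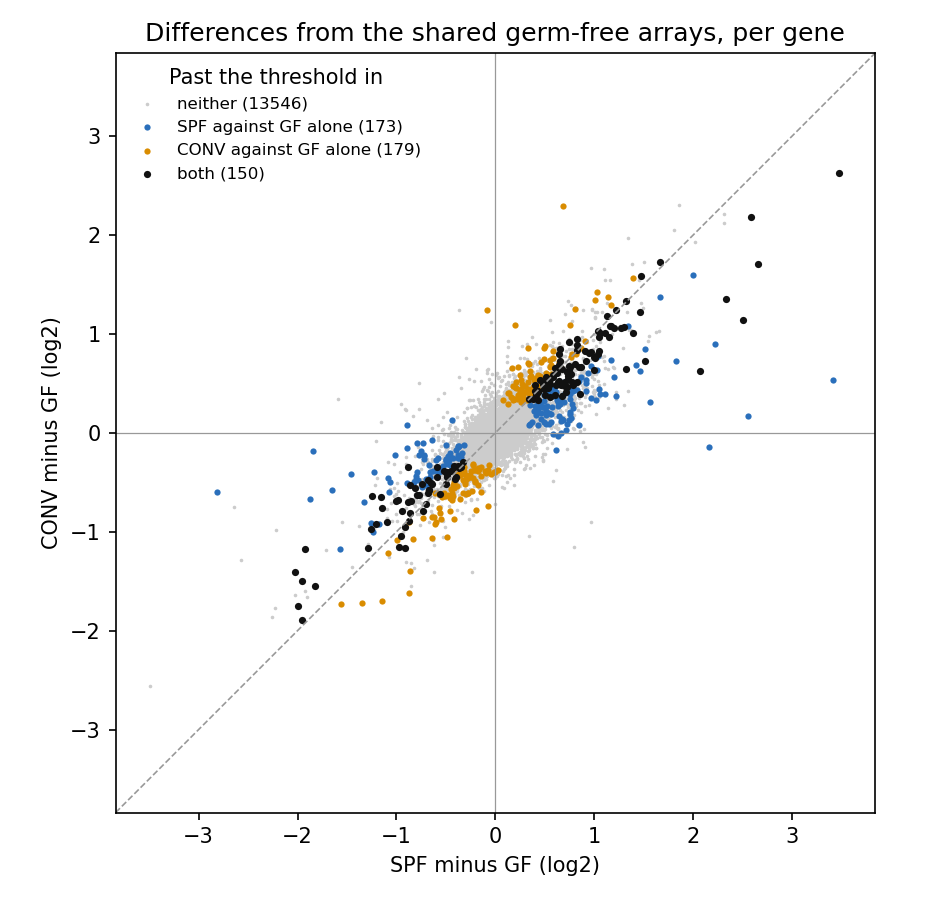
Log2 difference CONV minus GF (vertical axis) against SPF minus GF (horizontal axis) for 14048 genes, coloured by the comparison in which they passed the threshold, with the line of equal differences dashed. The 150 genes past the threshold in both lie at the lower left and upper right, and both axes use the same 3 GF arrays.

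CONV against SPF asked how colonised ex-germ-free livers differed from livers of mice raised with microbes. Ctse was higher in CONV by 1.66 ± 0.12 (adjusted p = 0.00395), while Papss1 fell by 1.44 ± 0.10 (adjusted p = 0.00395) and Saa2 by 2.88 ± 0.29 (adjusted p = 0.0335). A second, dimmer probe set of Ctse differed by 0.17. Of the fits that left out an array, Ctse and Papss1 kept their calls in 7 of 8, losing them without SPF replicate 2, and Saa2 in 1 of 8, losing it without each array except GF replicate 2. Saa1, Saa3 and Lcn2, chosen after their values were seen, differed by −2.39, −1.32 and −2.30 and did not pass (adjusted p = 0.139, 0.248 and 0.248). Ctse, Papss1 and Saa2 were the 3 genes that passed, with 1127 genes at an unadjusted p under 0.05. The next smallest p-values were those of Erdr1 (2.21, adjusted p = 0.0801), Cks1b (0.54), a cyclin-dependent kinase subunit, Fads2 (0.57) and Dhtkd1 (0.50) among genes higher in CONV, and of the adhesion molecule Icam1 (−0.67), Zc4h2 (−0.66) and Hdhd2 (−0.59) among genes lower in CONV. None of these passed, with adjusted p-values of 0.104 for Cks1b, Fads2, Icam1 and Zc4h2, 0.137 for Dhtkd1 and 0.110 for Hdhd2. The count was 10 without SPF replicate 1 and 0 without SPF replicate 2. The 7 clock genes did not pass, with Clock at −0.07 (adjusted p = 0.910), Per1 at 0.26, Per2 at 0.33, Arntl at −0.63, Cry1 at −0.22, Nr1d1 at 0.43 and Dbp at 1.28.

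By list, 7 passed with the preset correlation in CONV against SPF, and none with an estimated one. The acute phase list was lower in CONV (median −0.23, camera adjusted p = 1.12e-08; fry adjusted p = 0.0130; adjusted p = 0.119 with an estimated correlation), with 1 of 24 past the threshold and 8 adjusted over the list alone, which was 4 without SPF replicate 2. Macrophage markers were lower (median −0.59, camera adjusted p = 3.84e-08; adjusted p = 0.745 with an estimated correlation), with 0 of 14 members past the threshold in limma under either adjustment and 9 at an unadjusted p under 0.05. Its median was −0.23 without SPF replicate 1 and −0.91 without SPF replicate 2, and adjusted over the list alone 10 fell without GF replicate 1 and 12 without SPF replicate 2. Fatty acid synthesis (0.29), cholesterol synthesis (0.18), PPAR-alpha targets (0.09) and B and plasma cell markers (0.16) had medians above 0 and the interferon list (−0.17) below 0. Their camera adjusted p-values were 1.38e-05, 0.000759, 0.00169, 0.0277 and 0.00387, and with an estimated correlation the adjusted p was 0.745 for 4 of them and 0.684 for B and plasma cells. In these 5 lists 0 members passed over all genes in limma, with 5, 3, 2, 0 and 3 at an unadjusted p under 0.05 in the order above, and 1 of fatty acid synthesis rose adjusted over the list alone. For fatty acid synthesis that number was 10 and the median 0.43 without CONV replicate 1, and the median was 0.15 without CONV replicate 3. Without SPF replicate 1, the cholesterol, PPAR-alpha, interferon and B cell lists did not pass (adjusted p = 0.329, 0.493, 0.516 and 0.0983). Cholesterol synthesis did not pass without CONV replicate 3 (adjusted p = 0.262), nor interferon or PPAR-alpha targets without CONV replicate 2 (adjusted p = 0.230 and 0.0635). B and plasma cell markers did not pass without CONV replicate 1, CONV replicate 2 or SPF replicate 2 (adjusted p = 0.118, 0.0635 and 0.0745), and 4 lists passed without CONV replicate 2 and 12 without SPF replicate 2.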

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

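The tests of probe sets without a single gene name in this part were chosen after the gene results had been seen. These probe sets list several gene symbols or none and were left out of the comparisons of genes; 4016 of them passed the same low-signal filter. In limma, with adjustment over these probe sets, 38 passed the threshold in SPF against GF, 22 higher and 16 lower, against 639 at an unadjusted p under 0.05. In CONV against GF 25 passed, 13 higher and 12 lower, against 570 unadjusted. In CONV against SPF 1 passed, with a difference of −1.94, against 295 unadjusted. What these probe sets measure was not analysed here.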

How the results depend on the processing

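The results of lists without single arrays were chosen after the data were seen; the other alternatives were planned. Over all alternatives, named genes past the threshold kept their direction; in SPF against GF the call held in 620 combinations of gene and setting and was lost in 234, in CONV against GF in 487 and 234, and in CONV against SPF in 41 and 16. Most list calls held with the preset correlation: 94 held and 2 were lost for SPF against GF, 61 and 3 for CONV against GF, and 99 and 12 for CONV against SPF, where the direction of 1 test turned. No background level was given in the sources used here, so low signal is judged only by rank on the array, and dim probe sets can understate a difference.

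In SPF against GF, limma called 127 genes when only those groups were fitted, 836 with every probe set tested on its own, 164 with array weights and 989 at an adjusted p of 0.10. In CONV against GF it called 496 with the filter at the 60th percentile, 748 with every probe set on its own, 509 with eBayes trend and robust, 635 with array weights, 1140 at an adjusted p of 0.10 and 160 with at least 1.5-fold in addition. In CONV against SPF it called 0 with only those groups fitted, against 1127 unadjusted in the full fit, and 5 with the mean of a gene's probe sets. The number called in both SPF and CONV against GF was 77 with only the groups compared, 235 with trend and robust, 523 at an adjusted p of 0.10, 82 with at least 1.5-fold, and a median of 0 or 2 with the GF arrays split. Thresholds, filters and fewer arrays change counts by construction; for array weights, trend and robust, and the mean of probe sets the cause was not tested.

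With the replicate block limma called 26 genes in SPF against GF, 35 in CONV against GF, 0 in CONV against SPF and 11 in both SPF and CONV against GF; the cause was not tested. Arrays of the same number did not deviate together: for GF and CONV the correlations of their deviations from the group means were 0.108, −0.181 and 0.034. The arrays share only a number.

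For lists, an estimated correlation left 0 past the threshold in each of the 3 comparisons. Fry's one-way test left 1 in SPF against GF, 0 in CONV against GF and 1 in CONV against SPF. The 1 was the acute phase list each time. Fry's either-way test also passed other lists in each of the 3 comparisons, among them the clock list in those with GF. In CONV against SPF it passed bile duct markers, intestinal markers and fatty acid synthesis besides the acute phase list (fry adjusted p = 0.00763, 0.0261 and 0.0383 for the first 3). Without the low-signal filter 10 lists passed in SPF against GF. The cause was not tested for these.

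Leaving out each array in turn gave 26 to 539 genes in SPF against GF, 1 to 432 in CONV against GF, 0 to 10 in CONV against SPF and 1 to 213 in both. It gave 4 to 14, 3 to 6 and 4 to 12 lists for the 3 comparisons. These fits have fewer arrays, and with 1 SPF array left, that array is assumed to vary like the other groups.

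Values that changed sign belonged to genes that did not pass, and the test of the interferon list turned. In CONV against GF, Nr1d1 ranged from −0.079 without CONV replicate 3 to 0.146, and was −0.003 without GF replicate 1. In SPF against GF, Cry1 ranged from −0.112 without SPF replicate 1 to 0.906. In CONV against SPF, the ranges from without SPF replicate 2 to without SPF replicate 1 were −1.473 to 0.219 for Arntl, −0.218 to 0.073 for Clock, 0.619 to −0.109 for Per1, 0.962 to −0.299 for Per2, −0.729 to 0.289 for Cry1 and 2.639 to −0.077 for Dbp. The interferon list's median ranged from −0.518 to −0.006, where its test turned upward. The cause was not tested beyond the loss of that array.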

Other observations

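The tests in this part were chosen after the results were seen, except the counts over other divisions of the arrays. Some transcripts differed between SPF livers and both GF and CONV livers. At an unadjusted p under 0.001 in both limma comparisons, with SPF on 1 side of both groups, there were 27 genes, of which 7 also passed the threshold in CONV against GF. Simulated unchanged groups gave a mean of 2.86 such genes and at most 6 in 50 draws. The simulation drew each gene independently and with no group difference, whereas genes on these arrays vary together. The 2.86 is therefore no chance value for the 27. Ctse lay between 7.51 and 7.92 on the 6 GF and CONV arrays and at 6.06 and 5.76 in SPF, a difference that its second, dimmer probe set did not show (SPF minus GF −0.16). Erdr1 lay between 10.42 and 11.63 on the same 6 arrays and at 8.44 and 8.39 in SPF. Papss1 was graded, at 7.61 to 7.83 in GF, 8.18 to 8.46 in CONV and 9.76 and 9.75 in SPF, and its rise of 0.63 in CONV against GF passed in limma (adjusted p = 0.0334). No explanation was tested for these genes.

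Over the 21 clock genes, the difference between the SPF replicates correlated with CONV minus GF, which shares no array with it (r = 0.768 across genes, which are not independent replicates). Dilution of hepatocyte RNA by macrophage RNA would lower the hepatocyte markers, whose median was 0.014 (SD 0.069 over markers) in SPF minus GF. Quantile normalisation leaves the brightest probe sets little room to fall, so bright markers could hide dilution. The median therefore does not exclude it. Ciart lay at 5.94 and 5.88 in the SPF arrays and Clock at 9.07 and 8.78, but both passed the threshold, which favours a small spread, so this decides nothing about clock phase. Arrays caught at different clock phases are a candidate explanation, and a phase shifted by colonisation is another, which was not tested because the time of collection is not given in the sources used here. Over all genes the same correlation was 0.416, and 0.408 without the clock list. Pairs of GF arrays with CONV minus SPF gave absolute correlations of 0.012 to 0.035. In limma 3 genes passed in CONV against SPF and 329 in CONV against GF, so those pairs are a weak reference for the 0.416. A gradient shared by the spread within SPF and the difference between groups may reach beyond the clock, but these values cannot settle it.

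Macrophage markers were higher as a list in SPF than in GF livers, with 2 of 14 past the threshold, an adjusted p = 0.584 with an estimated correlation and a median of 0.55 without SPF replicate 1. A lower share of hepatocyte RNA would raise the markers of other cell types alike, but the endothelium median was 0.022 (SD 0.185 over markers) against 0.925 (SD 0.243) for macrophages. The higher values were not confined to SPF replicate 1, since 13 of 14 markers in SPF replicate 2 also lay above every GF array. These markers come from 1 array and are not independent, so the count cannot show how far SPF replicate 1 drives the pattern. The number of markers above every GF array was 4, 9 and 14 in CONV replicates 1, 2 and 3. More macrophages, or more of these transcripts per macrophage, after life with microbes remain open as hypotheses that may account for it and were not tested.

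Cholesterol synthesis genes were lower as a list in colonised livers, with 4 and 3 of 18 past the threshold in SPF and CONV against GF and adjusted p = 0.584 and 0.748 with an estimated correlation. Dilution of hepatocyte RNA would lower the hepatocyte markers, whose median was 0.041 (SD 0.098 over markers) in CONV minus GF. Bright markers have little room to fall after quantile normalisation, so the median does not exclude dilution. The list also differed between the SPF replicates, with a median of −0.229. The slope of the clock genes, applied to the list's own median of −0.429 in CONV minus GF, predicts −0.368. Outside the clock list the SPF difference also correlated with CONV minus GF (r = 0.408), so other lists changed in CONV may come near such a prediction. No other list was compared, so these values do not point to clock phase. If the arrays differ in clock phase, which remains a candidate explanation for the clock genes, such differences may contribute here too. An effect of colonisation itself was not tested apart from it.

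The 6 GF and CONV arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 329 genes and the highest other 1, so 1 of 10 divisions gave as many. Every other division mixes GF and CONV arrays, so a difference between GF and CONV widens its spread and lowers its gene count. The contrast of 329 with 1 is therefore partly built in. For lists the real division gave 4 and the highest other 10, and 7 of 10 gave as many. Part of the group difference can remain in the uneven mixtures, so the list counts do not decide the question either. These counts use the preset correlation of 0.01; with an estimated correlation 0 lists passed under the real division, and the other divisions were not run with it.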
